A study of Homo sapiens with 4 samples.

How the data were processed

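Total RNA from CAPAN2 cells, cultured with 10% serum and transduced in the presence of 8 µg/ml hexadimethrine bromide, was converted to biotinylated cRNA from 100 ng per sample, per the labels' protocols. The value table holds log2 signals of 54675 probe sets on 4 arrays, deposited by the authors after RMA summarisation, and Partek 6.6 was used, per the submitters' processing notes. The background step and the scan settings are not given in the sources used here. The scale was taken as log2 because the ratio of group means computed from it matched the authors' deposited table within 1.68e-05 on the log2 scale. A second deposited table gives the authors' comparison of the 2 groups: an unadjusted p-value, a ratio, a signed fold change and an F score, per the file headers. Its headers and the sample titles name the groups siLLGL1 and NC or siNC, while the other labels name lentivirus with shRNAs, so the reagent is given here as the latter state it. The ratio equals the arrays labelled LLGL1 shRNA over control in the value table.

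Probe sets were named from the platform annotation, of which 41097 carry 1 symbol, 1801 several and 11777 none. Entrez identifiers of 41043 were found in the reference gene table, which changed 0 symbols. The 62 control probe sets and those with several or no symbols were left out of the gene-level test. For each of 19775 genes the probe set with the highest mean over the 4 arrays was kept, a choice that mattered for 10523 genes with several probe sets. Differences were tested with lmFit and eBayes in limma 3.58.1 under R 4.3.3, without trend or robust priors, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 1.94 prior degrees of freedom, and the median SE of a log2 change was 0.0754. Values equal on both arrays of a group occurred in 2720 probe sets for control and 2747 for LLGL1 shRNA, which gives them a spread of 0 before moderation. The labels name biological replicates but not separate cultures or days, so p-values measure the spread between these arrays.

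The 27 gene lists (703 entries, 631 measured, the rest not analysed here) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives. Genes are named by this rule: LLGL1, LLGL2, SCRIB, DLG1, OSMR, IL6ST, STAT3 and SP1 always; the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays do not overlap between groups, uncharacterised loci skipped; and the 3 members with the largest absolute change, preferring those past the threshold, from each list that passed and from the polarity, oncostatin M and IL-6, ERK output, gemcitabine, epithelial and mesenchymal lists. Other list members are named where a count was 5 or fewer and were chosen after their values were seen. OSMR was chosen from general knowledge of work on LLGL1 in pancreatic cancer. That work may include these arrays, so the OSMR result cannot be taken as independent of it. The groups, the tests, the naming rule, the gene lists and most of the alternatives were fixed before the data were examined.

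Alternatives covered scaling (median centring, cyclic loess), moderation, a filter on the dimmer part of the probe sets, the mean of all probe sets of a gene, the replicate number as a block, leaving out each array, and stricter thresholds. The procedure was tested on simulated data for 19775 genes in 20 runs of this design, with 200 genes changed in each. It recovered 0.1% of genes changed 1.25-fold, 3.2% at 1.5-fold, 62.8% at 2-fold and 91.8% at 4-fold, and 4.13% of its calls were unchanged genes. The arrays gave 1242 calls, more than the genes changed in a run, so these shares do not carry over to them. Simulated variances came from limma's own fitted prior, with normal noise independent between genes, so a low share of unchanged genes was largely built in. Correlated genes, tied values and a shift by preparation of a group were not simulated.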

Results

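Gene expression was measured in CAPAN2, an established human pancreatic ductal adenocarcinoma cell line, after transduction with lentivirus. The comparison asked how depletion of LLGL1, a polarity protein of the lethal giant larvae family, changes the transcriptome of these cells. There were 4 arrays, 2 from cells given control lentivirus and 2 from cells given lentivirus with shRNAs against LLGL1. The labels call the 2 arrays of each group biological replicates. The deposited log2 signals had medians of 2.95 to 2.98 per array. Replicate arrays correlated across all probe sets at r = 0.997 in each group, and arrays of different groups at 0.993 to 0.994. These correlations are across probe sets, which are not independent replicates. The number of arrays limits the precision of every value below.

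The signal of LLGL1 itself was not measurably lower on the arrays labelled LLGL1 shRNA. The brightest of its 3 probe sets read 6.85 ± 0.0217 (log2, SD, n = 2) on the control arrays and 6.72 ± 0.0112 (SD, n = 2) on the arrays labelled LLGL1 shRNA. The log2 difference was -0.12 with a 95% interval of -0.27 to 0.02, and it did not pass limma's test (adjusted p = 0.22). Its dimmer probe sets differed by 0.09 and 0.06, and a probe set that the annotation assigns to both LLGL1 and FLII by 0.02. None of these passed. With the mean of all 3 probe sets the LLGL1 difference turned to 0.0079 (adjusted p = 0.96). The labels of the 2 groups were therefore not borne out by the targeted transcript, and every direction below is drawn between arrays as labelled.

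OSMR, the receptor subunit for oncostatin M, was higher on the arrays labelled LLGL1 shRNA. Its brightest probe set rose from 2.75 ± 0.227 (SD, n = 2) to 4.84 ± 0.0887 (SD, n = 2), a 4.26-fold difference (log2 2.09, SE 0.13, limma adjusted p = 0.0246) from a level below 3 on both control arrays. The next brightest OSMR probe set was 1.67 higher without passing the test (adjusted p = 0.19), its 2 control arrays reading 2.85 and 1.51, and the dimmest differed by 0.10. With the mean of the OSMR probe sets the log2 difference was 1.29 (adjusted p = 0.0363). The call was lost when every probe set was tested on its own (adjusted p = 0.0586). Without any 1 of the 4 arrays the log2 difference of OSMR was 1.93 to 2.25. Those fits leave 1 array in a group, so they do not bear on its call. IL6ST, the shared signalling subunit, differed by -0.14 and SP1 by -0.06 without passing. The transcription factor STAT3 differed by 0.24 (adjusted p = 0.173), its next dimmer probe sets by 0.33 and 0.38, and it passed under 2 of its alternatives, with trend and robust moderation (adjusted p = 0.0429) and among genes with a mean log2 of at least 5 (0.0254).

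**Figure D1:**
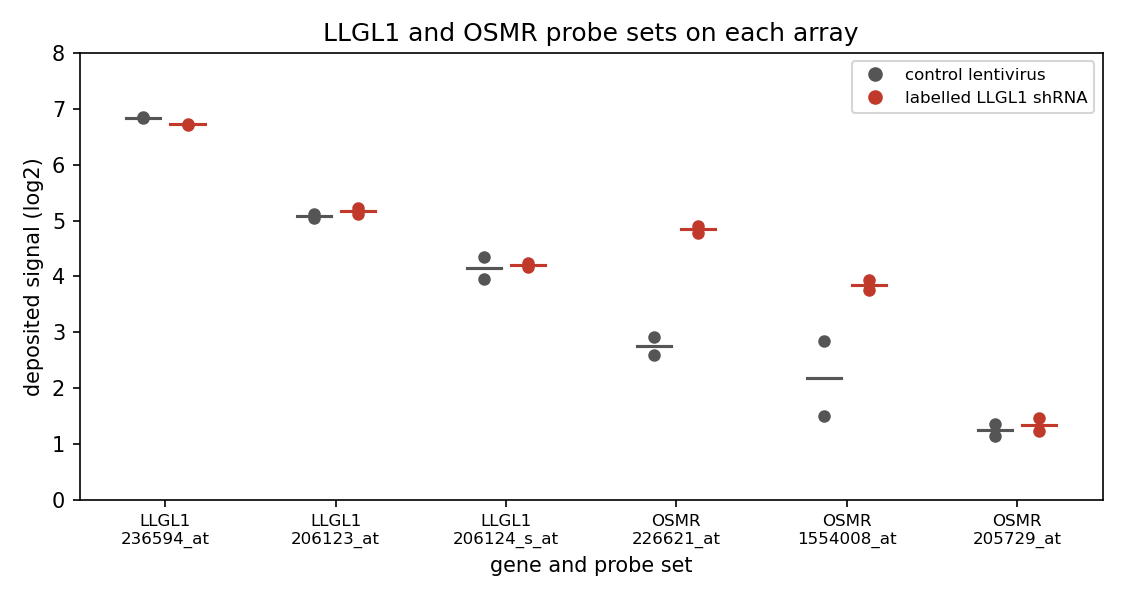
Deposited log2 signal of the 3 LLGL1 and 3 OSMR probe sets on each of the 4 arrays, with points for arrays and short lines for group means. The brightest LLGL1 probe set lies at 6.85 on control arrays and 6.72 on the arrays labelled LLGL1 shRNA, and the brightest OSMR probe set at 2.75 and 4.84.

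Across the transcriptome, 1242 of 19775 genes (6.28%) passed limma's test at an adjusted p below 0.05, 635 of them higher and 607 lower on the arrays labelled LLGL1 shRNA. Of these, 96 were at least 2-fold higher and 31 at least 2-fold lower. TCIM, a positive regulator of Wnt signalling, rose most, from 2.92 ± 0.12 to 6.50 ± 0.123 (log2, SD, n = 2 each), which is 11.9-fold. LIFR, the leukaemia inhibitory factor receptor, rose by 3.43 on the log2 scale (SE 0.0721), and BASP1 by 3.32. KCTD12 (log2 3.13), the glycoprotein hormone alpha subunit CGA (3.08), the fatty acid elongase ELOVL5 (3.02) and the extracellular matrix protein EFEMP1 (3.01) rose by similar amounts, followed by the heparan sulfate sulfotransferase HS6ST2 (2.81), DNER (2.77), the focal adhesion protein FERMT2 (2.69), the membrane-cytoskeleton linker MSN (2.68) and RAB31 (2.61). Adjusted p over these 12 genes ran from 0.00816 to 0.0326. LIFR, KCTD12, ELOVL5, HS6ST2, DNER, FERMT2 and RAB31 lay below 3 on both control arrays, and TCIM and MSN on 1 of them, with control means of 2.92 and 2.85. The size and rank of rises from such levels depend on the background step, which is not given in the sources used here. With the mean of all probe sets of a gene, in which dimmer ones take part, the log2 changes were smaller by over 1.5 times and still passed for LIFR (1.58), BASP1 (1.63), KCTD12 (1.82), CGA (1.64), ELOVL5 (0.94), HS6ST2 (1.58), FERMT2 (1.16) and MSN (1.31), so their order depends on the choice of probe set.

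ANKRD37, a gene induced by hypoxia, fell most in its brightest probe set, from 7.27 ± 0.0441 to 4.98 ± 0.123 (log2, SD, n = 2 each), which is 4.90-fold lower (limma adjusted p = 0.0114). The pyrimidine-catabolic enzyme DPYD (log2 change -1.63), the hyaluronan synthase HAS2 (-1.55) and NDRG1 (-1.53), another hypoxia-induced gene, fell next most. The log2 changes of IGFL1 (-1.45), the endothelial lipase LIPG (-1.45), LEMD1 (-1.44), TPT1-AS1 (-1.40), CLIC5 (-1.36), the lysosomal trafficking regulator LYST (-1.34), RAB3B (-1.30) and the placental alkaline phosphatase ALPP (-1.28) also passed. Dimmer probe sets of some named genes did not show the change of the brightest one: such a probe set differed by -0.07 for BASP1, -0.05 for MSN and -0.01 for LYST. With the mean of all probe sets of a gene, ANKRD37 changed by -1.22, less than NDRG1 (-1.53), HAS2 (-1.51) and IGFL1 (-1.45). DPYD (-0.70), CLIC5 (-0.66) and TPT1-AS1 (-0.34) shrank but passed, and LYST (-0.30, adjusted p = 0.0738) and RAB3B (-0.40, adjusted p = 0.0696) lost their calls. When each probe set was tested on its own, 68 passed. Fits without any 1 of the 4 arrays leave 1 residual degree of freedom and take the lone array to vary like the other group, and in limma 0 genes passed in them (3496 to 4546 at an unadjusted p below 0.05), with a lowest adjusted p of 0.187 to 0.262, so they say nothing about single calls. On the same arrays the poly-A spike and 18S ribosomal RNA controls were lower, as given with the control probe sets. Any difference in preparation between the groups would enter the gene changes as well.

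Genes of the cell cycle were higher together. Of 33 measured genes of the G2 and M phases, 14 rose and none fell (26 and 0 adjusted over the list alone), with a median log2 change of 0.38 (camera adjusted p = 5.8e-13, and adjusted p = 0.669 with an estimated correlation). AURKB, a mitotic kinase, rose by 0.87, UBE2C by 0.62 and CDCA8 by 0.59. Of 28 measured S-phase genes, 18 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 8.67e-13, and adjusted p = 0.669 with an estimated correlation). MCM5 (0.99) and MCM2 (0.95), subunits of the replicative helicase, and GINS2 (0.93) rose most in that list, while RFC5 fell (-0.51). GINS2 lost its call with the mean of its probe sets (log2 0.31, adjusted p = 0.0647). All 7 lists that passed with the preset correlation lost their call with an estimated one. Lists that had not passed, such as housekeeping genes and endothelial markers, had the same adjusted p of 0.669 in that camera test. That test therefore does not separate the 7 lists from these. It called 0 of 27 lists in this design with 2 residual degrees of freedom, so its 0.669 says little about any single list. The estimated correlation was 0.0274 for ERK output genes and 0.0178 for epithelial genes, near the preset 0.01, and both lost their call as well. For the other lists that passed it was higher: 0.36 for hypoxia and glycolysis, 0.22 for G2 and M, 0.16 for polarity, 0.15 for S phase and 0.069 for YAP and TAZ. The adjusted p at the preset 0.01 may therefore be too small for these lists.

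Genes of hypoxia and glycolysis were lower. Of 27 measured, 11 fell and 2 rose (17 and 4 adjusted over the list alone), with a median log2 change of -0.41 (camera adjusted p = 4.03e-05, and adjusted p = 0.669 with an estimated correlation). Besides ANKRD37 and NDRG1, the lipase inhibitor ANGPTL4 fell (-1.21). The 2 that rose were BNIP3 (1.21), from below 3 on both control arrays, and the glycolytic enzyme GPI (0.52). The output genes of ERK signalling were lower as well: 6 of 25 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.000199, and adjusted p = 0.669 with an estimated correlation). After cyclic loess 9 of them fell and 2 rose, and after median centring 10 and 2. The ERK phosphatase DUSP5 (-1.19), PHLDA1 (-0.94, or -0.59 as the mean of its probe sets) and the immediate early gene EGR1 (-0.70) fell, whereas MYC (0.67) and ETV4 (0.46) rose.

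The camera test at the preset correlation also put the epithelial and polarity lists lower, the latter with a median near 0. Among 31 genes of epithelial junctions and identity, 5 fell and 2 rose (6 and 2 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0101, and adjusted p = 0.669 with an estimated correlation). The keratin KRT19 fell (-0.61), and the other members that fell were CDH1 (-0.47), CGN (-0.42), ESRP1 (-0.39) and CTNNA1 (-0.35). The keratin KRT7 rose by 1.62 in its brightest probe set, with its other probe sets near 0. As the mean of all its probe sets, the brightest included, KRT7 differed by 0.44. The protease ST14 rose by 0.49, a call lost with the mean of its probe sets (adjusted p = 0.0843). Among 30 genes of the polarity complexes, PARD6B fell (-0.62, but -0.28 and adjusted p = 0.181 with the mean of its probe sets) and no member rose, 0 passed when adjusted over the list alone, and the median was -0.06 (camera adjusted p = 0.0413, and adjusted p = 0.669 with an estimated correlation). DLG1 differed by -0.46 (adjusted p = 0.0625) and PARD3B by -0.39 (-0.06 as the mean of its probe sets) without passing, though DLG1 passed under 6 alternatives (adjusted p from 0.0017 to 0.0371), median centring and cyclic loess among them, and PARD3B under 2 (0.0306 and 0.0439). Dimmer DLG1 probe sets differed by -1.05, -0.68, -0.52 and -0.48, and the remaining ones by 0.09 and 0.08. None of them passed when each probe set was tested on its own. The related genes LLGL2 (-0.03) and SCRIB (0.09) differed by less than DLG1 did in its brightest probe set. Among 21 YAP and TAZ targets, 7 fell and 4 rose (11 and 5 adjusted over the list alone), and the test put the list lower (camera adjusted p = 0.0407, and adjusted p = 0.669 with an estimated correlation). Its median was -0.31 and its mean 0.04, so the median and the mean differ in sign. The members with the largest rises were the forkhead factor FOXF2 (2.48), from a low level, and the matricellular genes CCN1 (1.81) and CCN2 (1.56). The polarity and the YAP and TAZ lists each lost their call when control_shRNA replicate 2 or LLGL1_shRNA replicate 2 was left out, and the YAP and TAZ list also without control_shRNA replicate 1. Both were also lost with median centring and without the dimmer probe sets. The polarity list was lost as well with cyclic loess, with fry and among genes with a mean log2 of at least 5.

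Receptors and ligands of the oncostatin M and IL-6 family did not stand apart from other genes as a list. Of 24 measured, 3 rose and none fell (7 and 2 adjusted over the list alone), namely LIFR, the cytokine IL6 (2.39, 5.23-fold) and OSMR. The list median was -0.06, its mean 0.33, and it did not pass (camera adjusted p = 0.55), while fry, which tests movement in one direction without comparison to other genes, put it higher (adjusted p = 0.0157). Of 25 mesenchymal genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.386, fry adjusted p = 0.0115, higher). The intermediate filament VIM rose 5.6-fold (log2 2.49, or 1.28 as the mean of its probe sets), FOXC2 by 1.40 (0.77 as the mean) and ZEB1 by 1.34, ZEB1 from below 3 on both control arrays and with its call lost under the mean of its probe sets (adjusted p = 0.0709). The gemcitabine list, named for a deoxycytidine analogue used against pancreatic cancer, had 24 measured genes, whose part in handling the drug was not tested. Of these, 3 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.386). After cyclic loess 6 of these rose and 2 fell, and after median centring 5 and 2. As deposited, the following passed. The nucleotidase NT5E fell (-1.06), and so did NT5C2 (-0.34). The nucleoside diphosphate kinase NME1 (0.67), the efflux pump ABCB1 (0.57, or 0.36 as the mean of its probe sets) and RRM2 (0.44) rose.

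The other lists did not pass. Cholesterol synthesis had 5 of 18 genes lower and 1 higher (camera adjusted p = 0.0515), the interferon response 3 of 38 higher and 2 lower (0.0742), and Wnt and beta-catenin targets 4 of 19 higher and 1 lower (0.0806). Squamous and basal genes had 4 of 20 lower and 1 higher (0.455), and the unfolded protein response 3 of 30 higher and 1 lower (0.541). NF-kB and inflammatory genes had 2 of 27 higher (0.654), IL6 among them, and the Notch pathway 1 of 26 higher and 2 lower (0.965). A single member passed in the housekeeping list (B2M, higher, 0.386), acinar markers (REG1A, higher, 0.386), the mucin and ductal list (S100P, lower, 0.474), cancer stem cell markers (CD24, lower, 0.836), endocrine markers (ISL1, higher, 0.91) and p53 targets (MDM2, higher, 0.965). No member passed among 12 fibroblast (0.792), 12 immune cell (0.654) and 10 endothelial markers (0.455), or among 39 ribosomal proteins (0.961). Adjusted over the list alone, 5 cholesterol genes fell and 1 rose, 8 interferon genes rose and 4 fell, 6 Wnt targets rose and 1 fell, 5 squamous genes fell and 2 rose, 7 genes of the unfolded protein response fell and 5 rose, 3 NF-kB genes rose and 4 fell, and 2 Notch genes moved each way. The housekeeping list then had 4 higher, the cancer stem cell list 1 in each direction, and the acinar, endocrine and mucin lists 1 each as before, while none of the p53 targets, ribosomal proteins or markers of other cells passed. These counts depend on the scaling. After cyclic loess the unfolded protein response had 5 higher and 5 lower, the p53 targets 4 and 1, the interferon response 7 and 3, Wnt targets 6 and 1, squamous genes 2 and 5, NF-kB genes 3 and 2, Notch genes 2 and 2 and cancer stem cell markers 1 and 1, with 3 housekeeping genes higher and 3 mucin genes lower. After median centring the unfolded protein response had 4 and 4 and the interferon response 5 and 3. Cholesterol synthesis passed as a list without control_shRNA replicate 1 and without LLGL1_shRNA replicate 1, and the squamous list without the dimmer probe sets. Median and mean differed in sign for the cancer stem cell, endocrine and p53 lists.

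**Figure D2:**
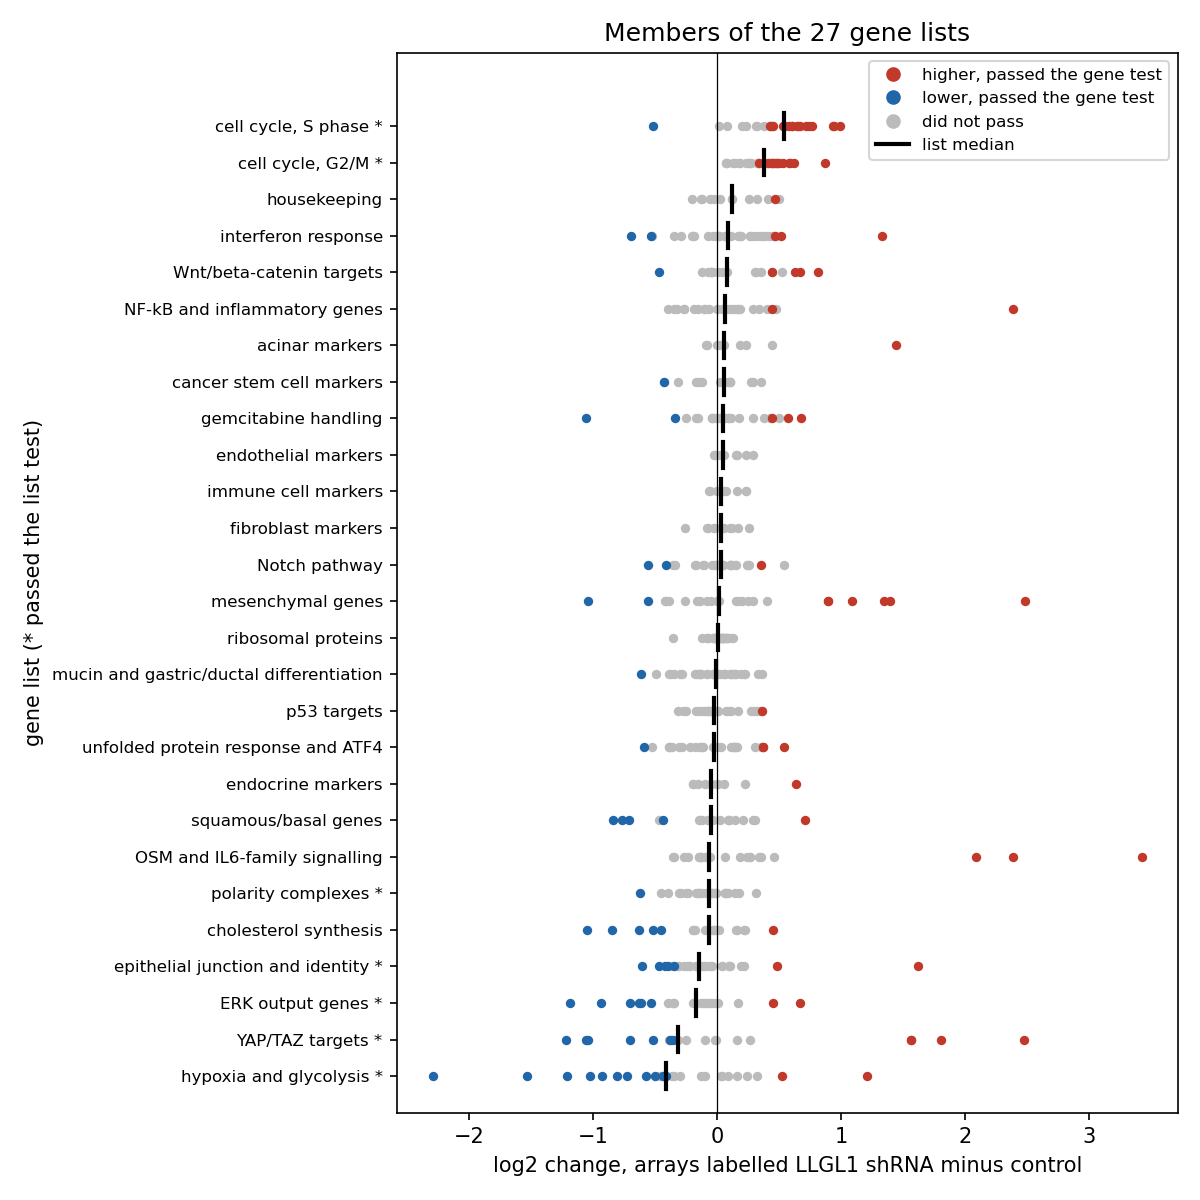
Log2 change of each measured member of the 27 gene lists (horizontal axis, arrays labelled LLGL1 shRNA minus control), ordered by list median (black bar), with members past the gene test in red or blue and the others in grey. The S-phase and G2/M lists lie highest, with medians of 0.54 and 0.38, and hypoxia and glycolysis lowest at -0.41.

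Class means of the control probe sets differed between the groups in both directions, but the probe sets that passed were all lower on the arrays labelled LLGL1 shRNA. The 24 probe sets for poly-A spike transcripts, bacterial RNAs added to total RNA before labelling, were lower by a mean log2 change of -1.14 on the arrays labelled LLGL1 shRNA, and 2 of them passed. The 3 probe sets for 18S ribosomal RNA all passed, with a mean change of -1.97, while those for 28S differed by a mean of -0.45, from -1.01 to 0.03, and none passed. The probe sets for ACTB differed by a mean of 0.46 and those for GAPDH by 0.09, and none passed. The 18 hybridisation controls, added after labelling, differed by -0.12 and none passed. Signs of these class means were the same after cyclic loess and after median centring, with 18S at -1.96 and -1.98. The arrays were already on a like scale and these steps moved the means little, so this is no independent test of sign.

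**Figure D3:**
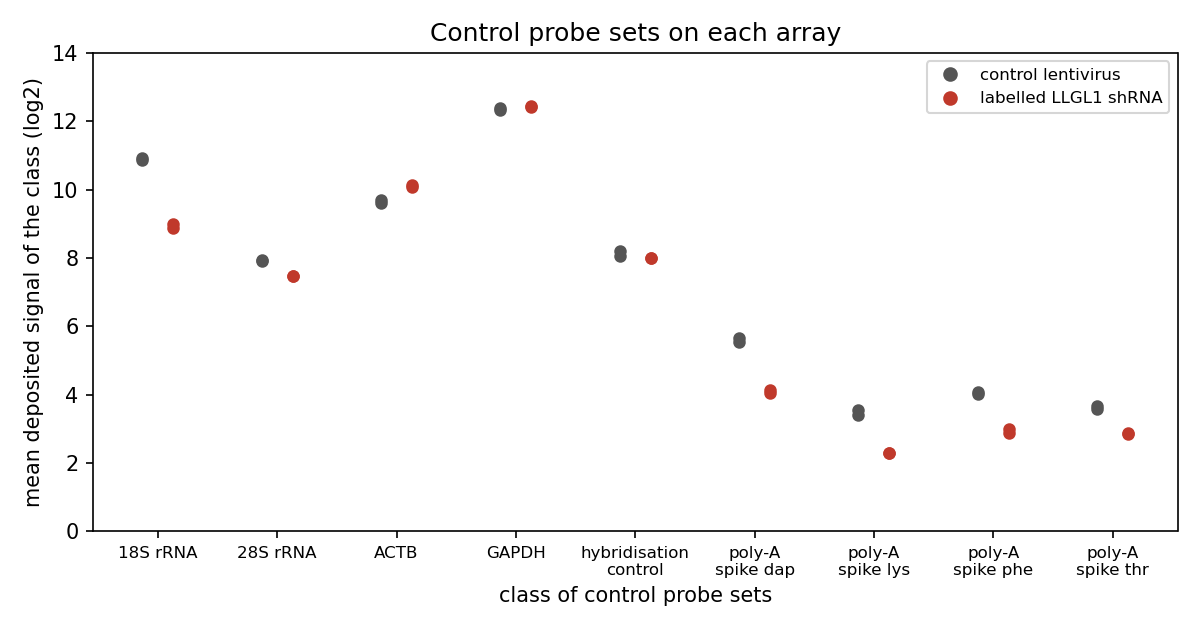
Mean deposited log2 signal of each class of control probe sets on each of the 4 arrays. The 18S ribosomal RNA and poly-A spike classes lie lower on both arrays labelled LLGL1 shRNA, with mean log2 changes of -1.97 for 18S and -1.14 over the 24 spike probe sets, against -0.12 for the hybridisation controls.

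The authors' deposited table lists 294 probe sets, 177 higher and 117 lower, with ratios from 0.204 to 22.6. It held each of the 294 probe sets whose group means differed at least 2-fold in the value table, 21 control probe sets included, with no limit on p: 16 of its rows have an unadjusted p of 0.05 or more, up to 0.172. Its rows name 193 distinct genes with a single symbol, of which 151 passed the gene-level test here. With each probe set tested on its own, over a larger number of tests, 68 of the 273 that are not control probe sets passed. With the control probe sets tested as well, 76 of the 294 did (25.9%).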

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

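The probe sets below were looked at only after their values were seen. Probe sets without a gene name in the annotation used here enter no gene-level comparison and were only counted in the test of every probe set. Among 11721 of them, 3 passed the test and were at least 2-fold higher on the arrays labelled LLGL1 shRNA than on the control arrays. Their log2 changes were 4.50, 2.81 and 1.20, and 1 probe set passed and was at least 2-fold lower (-1.13). The highest exceeds the change of TCIM, 3.58, which rose most among the genes tested.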

How the results depend on the processing

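The crossed pairing, the level filter of 5 and the probe-set test of OSMR and LLGL1 were added after seeing the data. The 1242 genes became 1881 with median centring, 2096 with cyclic loess (57.0% higher against 51.1%), 3935 with trend and robust moderation, 3241 without the dimmer probe sets, 3939 among 8379 genes with a mean log2 of at least 5, 479 at 1.5-fold or more, 68 with every probe set tested, 13 at an adjusted p below 0.01 and 6 without moderation. Leaving out any 1 array gave 0 to 0 (3496 to 4546 at an unadjusted p below 0.05), with a lowest adjusted p over all genes of 0.187 to 0.262 and 1 residual degree of freedom, which says nothing about which calls are stable. Other moderation, level filters and stricter thresholds leave the log2 change of a gene as it is, so its direction could not turn there. All 1242 kept their direction with median centring, with cyclic loess and without any 1 array. They had been called on these same arrays for changes large against the spread, so this is no independent test of direction. With the mean of all probe sets 1239 kept it, where 1210 passed and 813 were shared. For the other differences the cause was not tested.

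No label says that a replicate number marks a shared day or batch, and same-numbered arrays did not deviate together (r = -0.13 across genes), so the numbers were not used to pair arrays, and whether any batch is shared stays open. With the replicate number as a block, which also leaves 1 residual degree of freedom (lowest adjusted p 0.0945), 0 genes passed in limma (4284 at an unadjusted p below 0.05) and OSMR stayed at 2.09 (adjusted p = 0.123), while 7 lists passed. With crossed pairing 0 passed (5520 unadjusted).

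OSMR was also 2.09, past no threshold, without moderation (adjusted p = 0.133) and with every probe set tested (0.0586), and 1.93 to 2.25 without 1 array, and 1.29, still past the threshold, with the mean of its probe sets. Over its alternatives the adjusted p ran from 9.77e-05 to 0.262. LLGL1 turned to 0.0079 with the mean of its probe sets, which averages the dimmer ones in, and LLGL2 ran from -0.12 to 0.066 without 1 array, the latter without LLGL1_shRNA replicate 1. The 7 lists became 0 with an estimated correlation and 12 with fry, which tests each list on its own and added the oncostatin M and IL-6, mesenchymal, squamous, endocrine, NF-kB and Wnt lists, and 5 to 8 without 1 array, where cholesterol synthesis was gained without control_shRNA replicate 1 or LLGL1_shRNA replicate 1. The polarity list was lost with median centring, cyclic loess, fry, without the dimmer probe sets and at a mean log2 of at least 5, which also lost the epithelial list. The YAP and TAZ list was lost with median centring, without the dimmer probe sets and with the mean of probe sets. The 151 genes of the authors' table became 68 of 273 probe sets when each of 54613 probe sets was tested, which changes both the unit and the number of tests. Signals near background limit what can be read of genes below 3, where 33.3% of genes lie on both control arrays.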

Other observations

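All gene families and tests in this part were chosen after the gene table was seen. Genes of the cancer-testis antigen families, normally expressed in germ cells and in some tumours, were picked because some of them had risen, so no test of enrichment applies. Of 30 measured, 5 rose (16.7% against 3.19% of other genes) and none fell, and the median log2 change was 0.02. MAGEA6 rose by 2.48, MAGEB2 by 2.13, CT83 by 1.85, MAGEA1 by 1.60 and MAGEA12 by 0.77. Members of the MAGEA family are close paralogs, so their probe sets are not independent. MAGEA1, MAGEA6, MAGEB2 and CT83 also belong to the genes that rose from a low level, described last. The same number rose after cyclic loess and after median centring. Of 26 integrin subunits 2 rose and 2 fell, of 57 RAB GTPases 1 rose and 1 fell, and of 36 replication-dependent histones 1 rose and 0 fell. After cyclic loess these were 2 and 3, 2 and 3, and 4 and 0, and after median centring 2 and 2, 2 and 4, and 4 and 0.

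The LLGL1 signal was not measurably lower on the arrays labelled LLGL1 shRNA. An exchange of the labels of the 2 groups would put LLGL1 higher there by an unknown amount, and it stays open, since the highest upper 95% bound over its 3 probe sets was 0.49 on the log2 scale. Whether the probe sets read other RNA stays open, since the next brightest changed by 0.0915 and probe sequences were not used here. A depletion that is small, or not visible at the transcript level, also stays open and was not tested.

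The poly-A spikes and 18S ribosomal RNA were lower on the arrays labelled LLGL1 shRNA. Hybridisation or scanning is argued against by the hybridisation controls, whose mean change was -0.12, and RNA degradation by the gap between 3-prime and 5-prime probe sets of GAPDH and ACTB, which differed by at most 0.0283 between groups. Separate RNA or label preparation of the groups could give such a shift, which was -1.14 over the spikes. Such a preparation cannot be told apart from the shRNA, because no label gives a preparation batch. The same holds for the gene and list differences above, which compare the same arrays. A larger share of messenger RNA in the cells given the shRNA was not tested.

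Of genes below 3 on both control arrays, 32 were at least 2-fold above both on both arrays labelled LLGL1 shRNA, among them OSMR, LIFR and ZEB1, and 1 gene went the other way. The counts were 32 and 1 after cyclic loess and 33 and 1 after median centring. Noise near the floor, independent between arrays, is argued against by groupings with 1 array of each group on each side, which gave at most 0 such genes. A common shift left in the low deposited signals is argued against by the 6586 genes below 3 on both control arrays. Their median change was 0.0141, with an upper quartile of 0.11. The lower quartiles of the arrays were already alike, from 1.65 to 1.69. A common shift by background or scaling that earlier processing had removed would therefore not show here. A background step that acts on single probe sets differently was not tested. Fibroblasts, leukocytes or endothelial cells are argued against by 20 of their markers below 3 on control arrays. The highest log2 change among these markers was 0.26 and the median 0.0454, with COL1A2 at -0.03, COL3A1 at 0.02 and PTPRC at -0.06. RNA of another cultured line on both arrays may account for the 32 rises and cannot be told apart from a response of the CAPAN2 cells, because no such profile was used here. A response to LLGL1 shRNA, which the design names, stays an untested hypothesis.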
